A study of Homo sapiens with 4 samples.

How the data were processed

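RNA of exosomes and of cells from PNT2 and PC3M cultures was hybridised to Agilent human miRNA arrays, 1 array per sample and 4 in all, with 100 ng of RNA labelled with Cy3 per the labels' protocols. All arrays lay on 1 slide and were read in 1 scan per the file headers, so no slide or scan batch separates the groups. The labels give 1 sample for each of the 4 groups, and every file was mapped to its sample by the record of deposited files.

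The authors deposited the scanner output of each array, made with Agilent Feature Extraction 10.7.3.1 per the file headers. Its processed signal is an intensity on a linear scale in arbitrary units, and per the file headers spatial detrending was on while the separate background correction was off. Whether the authors scaled the arrays further is not given in the sources used here. The signal was below 0 for 39.9%, 37.1%, 38.9% and 38.1% of the human miRNA spots in PNT2 exosomes, PC3M exosomes, PNT2 cells and PC3M cells. The deposited value table of the series was compared with the scanner columns spot by spot. On all 4 arrays each of its 15739 values equalled the scanner's error estimate of the processed signal within 0.6%, and no more than 39 values per array equalled the signal itself. Its columns have medians of 2.75, 3.11, 3.05 and 2.71 units. The table is therefore a linear, uncentred measure of error and was not used for levels.

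Each array held 15739 spots, of which 13616 belonged to 2370 probes of 851 human miRNAs, with 1 to 4 probes per miRNA and 3 to 16 unflagged spots per probe. Control spots and spots flagged as non-uniform or population outliers were left out, except where all spots of a probe were flagged (765, 1076, 911 and 836 outlier spots in the same order). No human miRNA spot was saturated. The mean processed signal of a probe's spots was divided by the array's 75th percentile of it over the 158 probes detected on all 4 arrays, which was 309, 207, 488 and 559 units. A probe was called detected where at least 0.5 of its spots were well above background by the scanner's flag (multiplier 13 per the file headers). Scaled values were then floored at the lowest scaled signal among the detected probes of the array and put on a log2 scale. A miRNA took the value of its brightest probe, the one with the highest mean log2 value over the 4 arrays, and counted as detected where any of its probes did. For 1 of the 43 differences counted in exosomes and 1 of the 47 in PC3M this brightest probe was not itself detected on both arrays. Names are those of the array design without the species prefix, and the files give no probe sequence and no genome build, so that no position is printed. For viral probes and array controls the same scaling was used.

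4 comparisons were made: PC3M over PNT2 in exosomes and in cells, and exosome over cells in PNT2 and in PC3M. With 1 array per group there are no replicates, so differences were counted at 2-fold or more among miRNAs detected on both arrays, without a test. Spot-to-spot SDs of log2 signal were combined over the 2 arrays as the root of the summed squares. For a miRNA detected on 1 array the bound sets its value against the higher of its own signal and the lowest detected signal on the other array, and no fold is given where this is under 1. The difference of the exosome-over-cells values between the lines was taken over the miRNAs detected on all arrays. The number of arrays limits the precision of every value.

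The miRNAs named in the text followed a rule set before the data were examined. Per comparison these were the 8 highest and 8 lowest differences beyond 2 combined spot SDs, and the 3 largest bounds in each direction. For the difference between the lines the 5 highest and 5 lowest were taken. In addition miR-143, miR-145, miR-205, miR-99a, miR-100, miR-125b, miR-21, miR-148a, miR-126, miR-221, miR-222, miR-141, miR-200c and miR-210 could be named whatever their values, as could the 2 members of each list furthest from 0 in each direction and the 10 brightest miRNAs of an array. miR-155 in exosomes, miR-1225-3p, miR-1238, miRNAs named for detection on 1 array or on the arrays of 1 line only and the miRNAs of the closing section outside this rule were chosen after their values were seen. miRNA families and clusters, miRNAs reported as higher or lower in prostate tumours, markers of other cell types, G-rich entries, entries overlapping other small RNAs and passenger strands were listed beforehand. The lists of G-rich and other-small-RNA entries rest on names. Without probe sequences, G content and matches to other RNAs could not be computed. A list with at least 3 members measured on both arrays was described by its median and by the percentile of that median among 10000 random lists of equal size, matched on mean level in 10 bins. This describes these arrays and is not a p-value.

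The procedure was tested on simulated data. For each comparison the second array was copied with the spot and background noise of the first (seed 1), and 20 detected miRNAs were raised and 20 lowered 4-fold. In the simulation of PC3M over PNT2 exosomes, 19 of the 19 raised miRNAs left on both arrays and 10 of the 11 lowered ones were counted, and 9 lowered ones dropped out of detection. Among 126 miRNAs without a planted difference 0 were counted. In the simulation of PC3M exosome over cells the raised miRNAs counted were 20 of 20, the lowered ones 13 of 13, and 7 dropped out. A list of the raised miRNAs lay at percentile 100 in each simulation. The 2 arrays of a simulation differed only by the planted changes and by spot and background noise. The 126 unplanted differences had an SD of 0.07 (log2), and those of the other simulations 0.06 to 0.08. The 0 counts and the percentile of 100 therefore followed from the setting. Of 20 lists of unchanged miRNAs per simulation, 1 lay in the outer 5% of random lists in the cell comparison and 0 in the others. Variation between arrays or cultures and shifts from scaling were not simulated, and errors of these kinds are not covered.

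Alternatives were the 75th percentile over all miRNA probes, the median as reference, no scaling, quantile normalization, normexp background correction with an offset of 50 (limma 3.58.1 in R 4.3.3), detection in every spot, no detection filter, the mean over all probes of a miRNA, Agilent's own total gene signal and detection call, outlier-flagged spots kept, and a threshold of 4-fold. The rest was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.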

Results

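Small RNA was profiled on 4 single-colour microarrays, 1 for each of 4 samples: exosomes released by PNT2, exosomes released by PC3M, PNT2 cells and PC3M cells. PNT2 is an immortalised line of normal prostate epithelium and PC3M is a metastatic prostate cancer line. Exosomes are small membrane vesicles that cells shed into their medium. The study asked which miRNAs non-cancerous prostate cells release and how these compare with those of cancer cells. Each array carried probes for 851 human miRNAs. At least 1 probe was detected for 168 miRNAs in PNT2 exosomes, 145 in PC3M exosomes, 164 in PNT2 cells and 167 in PC3M cells. In all, 226 miRNAs were detected on at least 1 array, 105 on every array and 625 on none. The lowest detected probe signal was 11.6 units in PNT2 exosomes, 7.61 in PC3M exosomes, 12.8 in PNT2 cells and 13.2 in PC3M cells. Single negative control spots had SDs of 6.60 and 9.48 units on the exosome arrays of PNT2 and PC3M and 3.29 and 3.76 on the cell arrays, with 1, 15, 4 and 3 of 434 well above background. The lowest detected signal in PC3M exosomes thus lay within 1 such SD, and dim detections and bounds that involve that array carry more doubt. The brightest probe reached 61629, 49944, 33124 and 42481 units in the same order. Each group had 1 array, so no difference has a replicate check, no test was run, and no p-value is given. Errors are SDs over the spots of a probe within an array and cover spot error only. Their median over detected miRNAs was 0.09, 0.14, 0.08 and 0.09 (log2) in the same order. Differences between groups are log2 values after scaling. A miRNA not well above background on 1 array has only a bound, given as at least N-fold.

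miR-143 and miR-145, which share a cluster and are widely reported as low in prostate tumours, were not well above background on any array. The probe used for miR-143 read -2.42 ± 3.78 units in PNT2 exosomes, 1.07 ± 5.53 in PC3M exosomes, -0.55 ± 2.0 in PNT2 cells and -1.45 ± 2.66 in PC3M cells (SD, 8 spots each). That of miR-145 read -2.40 ± 2.5, -0.95 ± 3.55, -0.13 ± 2.57 and -0.53 ± 1.88 in the same order. No fold was therefore given for either miRNA in any comparison. miR-21, an abundant miRNA of epithelial and tumour cells, was detected on all 4 arrays, at 19187 ± 230 units in PNT2 exosomes and 42481 ± 1263 in PC3M cells.

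**Figure D1:**
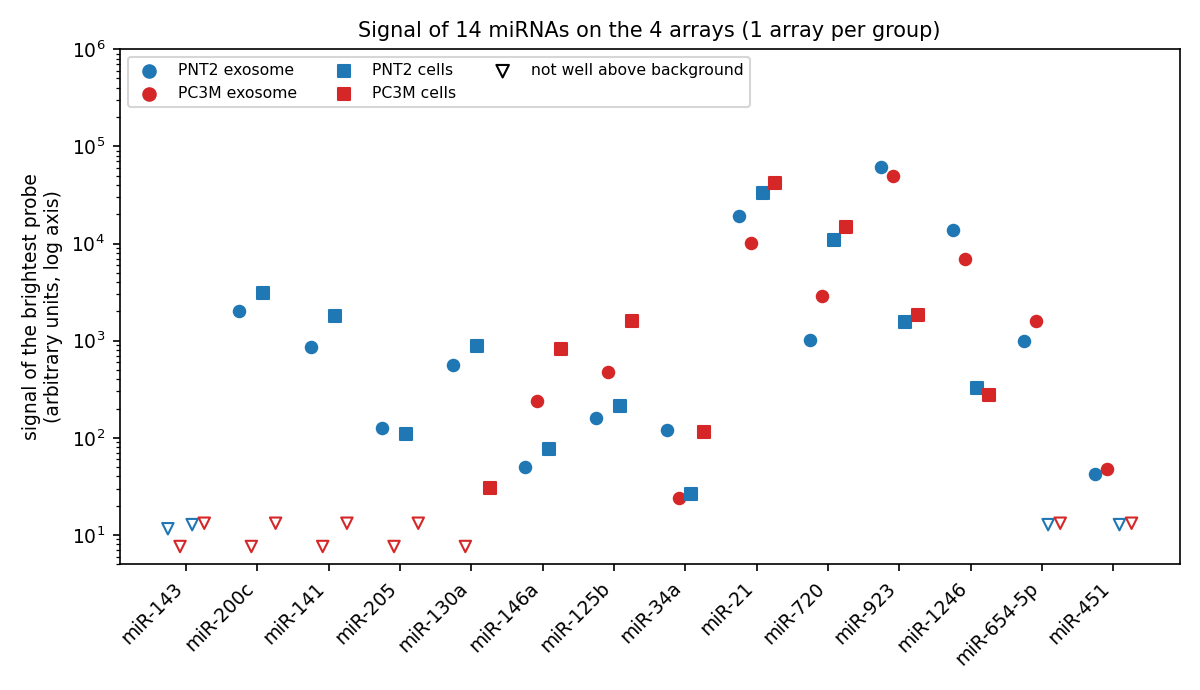
Signal of the brightest probe (arbitrary units, log axis) of 14 miRNAs on each of the 4 arrays; circles are exosomes, squares are cells, blue is PNT2, red is PC3M, bars are the SD over spots and mostly lie within the symbols, and open triangles mark the lowest detected signal of an array on which the miRNA was not well above background. miR-200c read 3103 units in PNT2 cells and was not well above background in PC3M, while miR-923 read 61629 units in PNT2 exosomes and 1564 in PNT2 cells.

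The first comparison asked how the exosomes of the cancer line differed from those of the normal line. The epithelial miRNAs miR-200c and miR-141, which repress the ZEB transcription factors, were detected in PNT2 exosomes and not in PC3M exosomes, where they were at least 176-fold and at least 74.8-fold lower. miR-130a was at least 49.6-fold lower, miR-155 at least 17.5-fold and miR-205, a miRNA of basal prostate epithelium, at least 11.0-fold. miR-30a was 13.8-fold lower (log2 -3.79, combined spot SD 0.38), miR-200b 11.2-fold (-3.48, SD 0.10) and miR-193b 7.29-fold (-2.87, SD 0.40). In the other direction miR-146a, a regulator of NF-κB signalling, was 7.25-fold higher in PC3M exosomes (2.86, SD 0.12). miR-100 was 5.32-fold higher, let-7i 4.64-fold and miR-125b 4.43-fold.

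Of 127 miRNAs detected in both exosome samples, 24 were at least 2-fold higher in PC3M and 19 at least 2-fold lower. A further 18 were detected only in PC3M exosomes and 41 only in PNT2 exosomes. For 10 and 23 of these the bound itself reached 2-fold. Levels in the 2 samples correlated across these miRNAs at r = 0.87 (Spearman 0.81), where miRNAs are not independent replicates. All but 1 of the 43 differences exceeded 2 combined spot SDs, and the 19 that could be read from at least 2 probes had the same sign in each. The other named members with higher values were miR-720 (log2 2.06), miR-760 (1.95) and miR-494 (1.92). miR-610 was counted among the 24, but no single probe of it was detected on both arrays and no value is given. Those with lower values were miR-30c (-1.95), miR-15a (-1.83), miR-34a (-1.77), miR-103 (-1.62) and miR-29b (-1.48). miR-9* was at least 7.66-fold higher in PC3M exosomes, miR-125b-2* at least 4.86-fold and miR-551b at least 3.70-fold.

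By group, 6 of 8 measured entries that overlap other small RNAs, mainly tRNA fragments, were at least 2-fold higher in PC3M exosomes (median 1.49, percentile 99.98 among 10000 random lists matched on level). They included miR-1260 at 1.65, while the 2 probes of miR-1290 differed in sign (-0.50 and 0.50), and miR-886-3p was detected only in PNT2 exosomes (at least 2.32-fold lower in PC3M). With the 75th percentile over all miRNA probes 1 of the 8, miR-720 (1.24), stayed at least 2-fold higher and 2 were at least 2-fold lower (median 0.67), and without scaling 3 were higher and 1 lower. All 5 members of the miR-30 family had negative values and 4 were at least 2-fold lower (median -1.47, percentile 0.72). In the miR-15/16 family 3 of 4 were at least 2-fold lower (median -1.35, percentile 2.94). In the miR-99/100 and miR-125 families 2 of 3 were at least 2-fold higher (median 2.15, percentile 97.56), with miR-125a-5p at -0.51 and miR-99b detected only in PNT2. Of the 5 members of the miR-200 family, which holds epithelial cells in their state, 4 were detected only in PNT2 exosomes. Of 9 let-7 members, let-7i was at least 2-fold higher and let-7d (-1.27) at least 2-fold lower (median -0.56, percentile 11.0), but 5 were lower with the 75th percentile over all miRNA probes or without scaling and 0 with the median as reference. Of the cluster of miR-183, miR-96 and miR-182, miR-183 was 3.42-fold higher (1.78), and 0.96 with the 75th percentile over all miRNA probes. All 11 measured members of the miR-17-92 cluster and its paralogues differed by less than 2-fold, but 5 were at least 2-fold lower with the 75th percentile over all miRNA probes and 3 higher with quantile normalization. The 3 measured members of the family of miR-130 and miR-301 differed by less than 2-fold, while miR-130a and miR-454 were detected only in PNT2 (at least 49.6-fold and 2.82-fold lower). The 4 of the miR-320 family also differed by less than 2-fold. The miR-23/27/24 clusters had 1 of 5 at least 2-fold lower (miR-23b, -1.29) and the miR-29 family 1 of 3 (miR-29b). With the 75th percentile over all miRNA probes 3 were lower in each of these groups, and with the median as reference 0 and 1. Of miRNAs reported as higher in prostate tumours 9 were measured, 1 of them at least 2-fold higher, with a median of 0.66 (percentile 98.26). This median turned to -0.16 when arrays were scaled over all miRNA probes. Without the detection filter it was -0.02, the difference of the 2 array floors, which any miRNA detected on neither array takes. Of this list miR-200c, miR-141 and miR-148a were detected only in PNT2 exosomes. Of those reported as lower 6 were measured, 2 at least 2-fold higher and 2 at least 2-fold lower (median 0.16), and 3 more, miR-205, miR-222 and miR-224, were detected only in PNT2 exosomes. For miR-222 only the detection call differed, as its scaled value was not lower in PC3M exosomes (0.11) and no bound is given.

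The balance of higher and lower values depended on the scaling. It was 24 to 19 as reported, 8 to 50 with the 75th percentile over all miRNA probes, 12 to 42 without scaling and 35 to 15 with the median as the reference. These settings shifted the median difference by -0.82, -0.58 and 0.29, and quantile normalization by 0.24.

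The second comparison asked how the cells themselves differed. In PC3M cells miR-200c, miR-141, miR-155 and miR-205 were again not well above background. They were at least 269-fold, 154-fold, 20.7-fold and 9.48-fold lower than in PNT2 cells. miR-130a was 33.0-fold lower (log2 -5.05, SD 0.09), miR-30a 16.7-fold (-4.06, SD 0.22), miR-193b 9.91-fold (-3.31, SD 0.08) and miR-429 9.83-fold (-3.30, SD 0.14). miR-146a was 9.22-fold higher in PC3M cells (3.21, SD 0.15), let-7i 7.21-fold (2.85, SD 0.12), miR-100 6.65-fold (2.73, SD 0.08) and miR-125b 6.46-fold (2.69, SD 0.06). miR-34a, a target of p53, was 3.84-fold higher in PC3M cells (1.94, SD 0.16), whereas it was 3.41-fold lower in PC3M exosomes.

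Of 145 miRNAs detected in both cell samples, 12 were at least 2-fold higher in PC3M and 22 at least 2-fold lower, and all 34 exceeded 2 combined spot SDs. Levels correlated across miRNAs at r = 0.87 (Spearman 0.83). Another 22 were detected only in PC3M cells and 19 only in PNT2 cells, with a bound of 2-fold or more for 6 and 9. The remaining named miRNAs with higher values were miR-193a-3p (2.37), miR-625 (2.27) and miR-96 (1.58). Those with lower values were miR-200b (-2.94), miR-200a (-2.87), miR-7 (-2.48) and miR-30c (-2.28). miR-9* was at least 7.07-fold higher in PC3M cells, miR-99a at least 5.37-fold and miR-9 at least 5.34-fold. miR-126 was 3.46-fold lower, the hypoxia-induced miR-210 2.83-fold lower and miR-148a at least 3.76-fold lower. miR-221 and miR-222, which form a cluster, were at -0.27 and 0.66, and miR-21 at 0.16.

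In the miR-200 family 3 of 3 measured members were at least 2-fold lower in PC3M (median -2.94, percentile 0.20) and the other 2 were detected only in PNT2. In the miR-30 family 4 of 5 were at least 2-fold lower (median -2.04, percentile 1.85), in the miR-181 family 2 of 3 (median -1.43, percentile 9.66) and in the miR-15/16 family 1 of 4 (median -0.71, percentile 1.98). With quantile normalization or the 75th percentile over all miRNA probes, 1 of the miR-181 family and 0 of the miR-15/16 family were left, and 1 of 11 of the miR-17-92 group was at least 2-fold higher. The family of miR-130 and miR-301 had 1 of 5 at least 2-fold lower, miR-130a, with the others between -0.61 and 0.09. In the miR-99/100 and miR-125 families 2 of 4 were at least 2-fold higher (median 1.44, percentile 98.10) and miR-99a was detected only in PC3M. miR-96 and miR-183 were both at least 2-fold higher. The let-7 family had 1 of 9 at least 2-fold higher (let-7i; median 0.20, percentile 97.81). As scaled here, no measured member of the miR-17-92 cluster and paralogues, the miR-23/27/24 clusters, the miR-29, miR-26 or miR-320 families, the G-rich entries or the entries that overlap other small RNAs differed by 2-fold. Of the last group miR-886-3p was detected only in PNT2 cells and was at least 14.4-fold lower in PC3M. Of 7 measured miRNAs reported as lower in prostate tumours, 3 were at least 2-fold higher in PC3M cells, miR-100, miR-125b and miR-34a (median 0.66, percentile 99.62). Without the detection filter the median was -0.15, the difference of the 2 array floors, which any miRNA detected on neither array takes. Outside these 7, miR-205 and miR-224 were detected only in PNT2 cells (at least 9.48-fold and 7.84-fold lower in PC3M) and miR-99a only in PC3M cells. Of 10 measured miRNAs reported as higher, 2 were at least 2-fold higher (miR-96, miR-183) and 1 lower (miR-210; median 0.29, percentile 99.93), while miR-200c, miR-141 and miR-148a were detected only in PNT2 and miR-182 only in PC3M.

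The split of 12 higher and 22 lower in cells became 20 and 17 with the 75th percentile over all miRNA probes and 17 and 16 with quantile normalization, which shifted the median by 0.43 and 0.26.

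Over the 105 miRNAs detected on every array, the difference between the lines in exosomes correlated with that in cells at r = 0.74 (Spearman 0.58), from arrays that the 2 differences do not share. Both differences were at least 2-fold higher in PC3M for 8 miRNAs and at least 2-fold lower for 8. Of the same 105, 16 were higher and 19 lower by 2-fold in exosomes, and 10 higher and 10 lower in cells. Detection on both PNT2 arrays and neither PC3M array applied to 10 miRNAs, led by miR-200c, miR-141, miR-155 and miR-205. The reverse applied to 3, miR-9*, miR-551b and miR-10b.

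**Figure D2:**
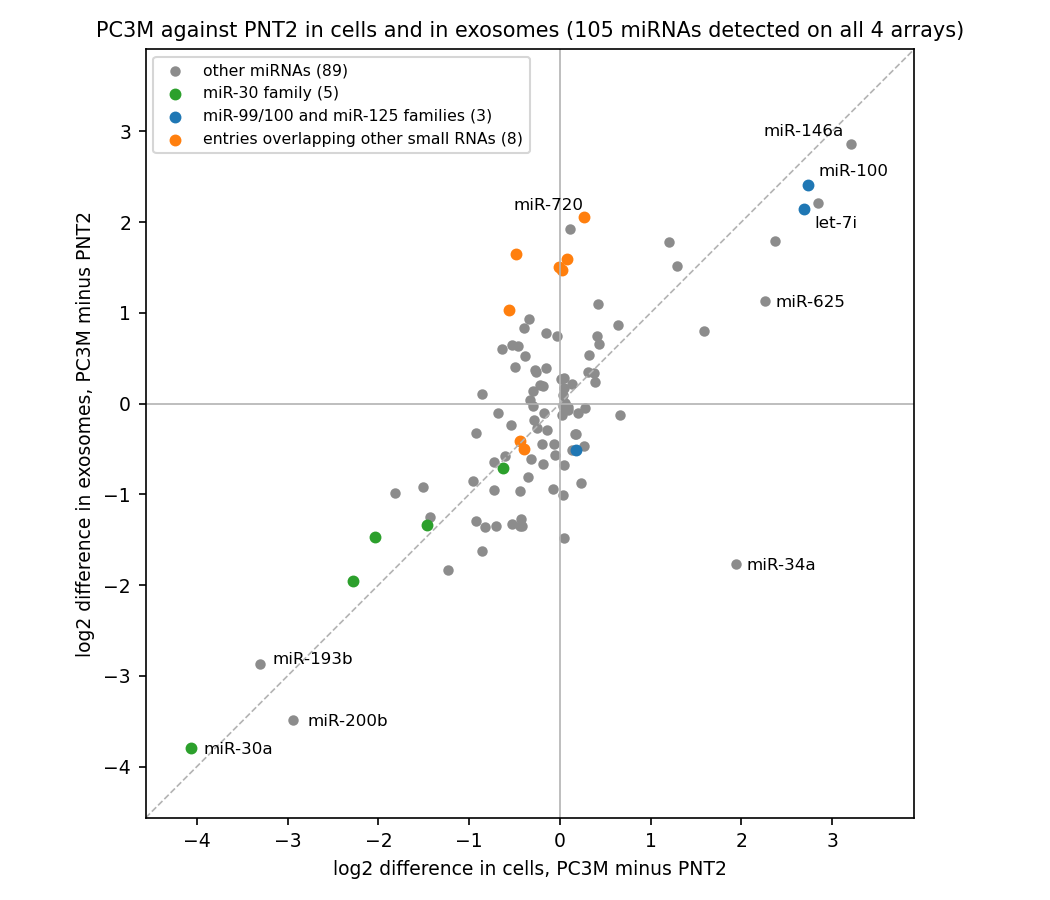
Log2 difference between PC3M and PNT2 in cells (x axis) and in exosomes (y axis); each point is 1 of the 105 miRNAs detected on all 4 arrays, the dashed line marks equal differences, and 3 fixed groups are coloured. Most points with large differences lie near the line, from miR-30a at -4.06 and -3.79 to miR-146a at 3.21 and 2.86, while miR-34a lies at 1.94 and -1.77.

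The third comparison asked which RNAs PNT2 exosomes held at other levels than the PNT2 cells. Most miRNAs had similar scaled levels: 118 of the 139 detected in both differed by less than 2-fold, among them miR-21 (-0.13), miR-200c (0.02), miR-141 (-0.41), miR-100 (0.27) and miR-125b (0.23). Those with the highest values in exosomes were mainly G-rich or doubtful miRNA entries. miR-638 was 90.3-fold higher in exosomes (6.50, SD 0.12), miR-1246, which overlaps U2 small nuclear RNA, 65.9-fold (6.04, SD 0.07), and miR-923, an entry since withdrawn as a fragment of ribosomal RNA, 62.2-fold (5.96, SD 0.05). miR-654-5p was at least 124-fold higher. Entries that match tRNA were lower in exosomes: miR-1260 18.4-fold (-4.20, SD 0.12), miR-720 6.69-fold (-2.74, SD 0.09) and miR-1274b 6.67-fold (-2.74, SD 0.08). Among established miRNAs miR-34a stood out at 7.28-fold higher (2.86, SD 0.16).

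In PNT2, 13 of the 139 miRNAs were at least 2-fold higher in exosomes and 8 at least 2-fold lower, all 21 by more than 2 combined spot SDs. Only in exosomes 29 were detected and only in cells 25, with bounds of 2-fold or more for 23 and 2. Levels correlated across miRNAs at r = 0.74 (Spearman 0.76). miR-1202, miR-1290, miR-1915, miR-1225-5p and miR-1268 were higher by log2 values of 5.69, 5.69, 5.63, 5.36 and 5.18. miR-1274a (-2.67), miR-886-3p (-1.99), miR-1308 (-1.80), miR-574-3p (-1.69) and miR-17* (-1.49) were lower. In 1 of the 8 cases with at least 2 measured probes the probes differed in sign. Of miRNAs not detected in cells, miR-630 was at least 31.4-fold higher and miR-939 at least 28.3-fold. Of those not detected in exosomes, miR-19b-1* and miR-374a were at least 2.15-fold and 2.14-fold lower and miR-33a at least 1.93-fold.

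Of 11 measured G-rich entries 7 were at least 2-fold higher in PNT2 exosomes and 4 differed by less (median 3.83, percentile 100 of 10000 matched lists), and 10 more were detected only there. Of 9 entries that overlap other small RNAs, 6 were at least 2-fold lower and 2, miR-1246 and miR-1290, at least 2-fold higher (median -1.99, percentile 0). The let-7 family lay between -0.72 and 0.09 (median -0.47, percentile 5.60) and the miR-17-92 group between -0.94 and 0.25, with no member at 2-fold, but with the 75th percentile over all miRNA probes 5 and 6 members were at least 2-fold lower. As scaled here, the miR-200, miR-99/100 and miR-125, miR-15/16, miR-23/27/24, miR-29, miR-30, miR-26, miR-148, miR-130 and miR-181 groups, the clusters of miR-221 and of miR-183 and the miRNAs reported as higher in prostate tumours had no member at 2-fold either. With the 75th percentile over all miRNA probes 2 of 5 miR-200, 3 of 5 miR-23/27/24, 2 of 3 miR-29 and 2 of 4 miR-15/16 members were at least 2-fold lower, as were 1 of 4 in the miR-99/100 and miR-125 families, 1 of 2 in the miR-183 cluster and 3 of 12 reported as higher. Of the 9 measured miRNAs reported as lower, miR-34a was the 1 at 2-fold. With the 75th percentile over all miRNA probes miR-31 and let-7c also reached 2-fold, both lower in exosomes. In the miR-320 family 1 of 4 was at least 2-fold higher, miR-320a, and the median of 0.65 (percentile 97.64) turned to -0.01 without scaling.

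The split of 13 to 8 in PNT2 became 12 to 42 with the 75th percentile over all miRNA probes, 12 to 44 without scaling and 12 to 27 with quantile normalization. Their shifts of the median were -0.65, -0.66 and -0.41. Without the G-rich and other-small-RNA entries, left out after the data were examined, 4 higher and 2 lower remained.

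The fourth comparison did the same in the cancer line. In PC3M exosomes miR-923 was 73.3-fold higher than in the cells (6.20, SD 0.05), miR-630 70.6-fold (6.14, SD 0.31), miR-1246 66.9-fold (6.06, SD 0.07) and miR-1915 66.7-fold (6.06, SD 0.22). miR-654-5p was at least 327-fold higher. miR-29b was 4.84-fold lower in exosomes (-2.28, SD 0.04), miR-1260 4.22-fold (-2.08, SD 0.15) and let-7f, of the let-7 family that restrains growth, 3.24-fold (-1.69, SD 0.04). miR-34a was at -0.84, on the other side of 0 from its value in PNT2.

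Of 111 miRNAs detected in both PC3M samples, 27 were at least 2-fold higher in exosomes and 20 at least 2-fold lower, all 47 beyond 2 combined spot SDs. Another 34 were detected only in exosomes and 56 only in cells, with bounds of 2-fold or more for 31 and 6. Levels correlated across miRNAs at r = 0.64 (Spearman 0.67). The remaining named miRNAs with higher values were miR-1202 (5.76), miR-1290 (5.58), miR-638 (5.45) and miR-1268 (5.27), and miR-671-5p and miR-939 were at least 42.3-fold and 30.5-fold higher. Those with lower values were miR-125a-5p (-1.64), let-7e (-1.58), let-7a (-1.43), miR-31 (-1.42) and miR-15b (-1.42). miR-17*, miR-9 and miR-21* were at least 5.18-fold, 3.51-fold and 3.04-fold lower. As scaled here, miR-100 (-0.05), miR-125b (-0.32), miR-21 (-0.63), miR-221 (0.53) and miR-210 (0.38) differed by less than 2-fold, although the other probe of miR-21 gave -1.10. Without scaling miR-100 was at -1.48, miR-125b at -1.75, miR-21 at -2.06, miR-221 at -0.90 and miR-210 at -1.05.

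All 11 measured G-rich entries were at least 2-fold higher in PC3M exosomes (median 5.21, percentile 100), and 8 more were detected only there and miR-1238 only in cells. With the 75th percentile over all miRNA probes 7 of the 11 remained so, and for miR-1225-3p no single probe was detected on both arrays. For miR-1238 only the detection call favoured cells: it read 14.8 units in exosomes and 16.4 in cells, before division by 207 and 559. The let-7 family had 5 of 9 members at least 2-fold lower (median -1.09, percentile 1.96), the miR-29 family 2 of 3 (median -1.08, percentile 4.90) and the miR-15/16 family 2 of 4 (median -1.01, percentile 5.93). Of 8 entries that overlap other small RNAs 3 were at least 2-fold lower and 2 at least 2-fold higher (median -0.62, percentile 18.2). The miR-17-92 group had 2 of 11 at least 2-fold lower. With the 75th percentile over all miRNA probes all 9 let-7, 3 miR-29, 4 miR-15/16 and 11 miR-17-92 members were at least 2-fold lower, and without scaling 9, 3, 4 and 10. In the miR-320 family 3 of 4 were at least 2-fold higher, with a median of 1.24 (percentile 97.22) that turned to -0.66 with the 75th percentile over all miRNA probes and to -0.20 without scaling. In the miR-30 family miR-30d (1.19) was at least 2-fold higher, which turned to -0.71 and -0.24 under the same 2 settings. Among miRNAs reported as lower in prostate tumours 1 of 6 was at least 2-fold lower (miR-31), and among those reported as higher 1 of 9 (miR-96, -1.31), while all 6 and all 9 were lower by 2-fold with the 75th percentile over all miRNA probes and 5 and 7 without scaling.

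The split of 27 to 20 became 11 to 82 with the 75th percentile over all miRNA probes, 12 to 69 without scaling and 15 to 37 with quantile normalization. These settings shifted the median by -1.90, -1.44 and -0.62. Of the 27 higher values 13 kept their sign under every scaling.

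Between the lines, the exosome-over-cells differences of the 105 shared miRNAs correlated at r = 0.91 (Spearman 0.84), again with no array in common. In both lines 12 miRNAs were at least 2-fold higher in exosomes and 4 at least 2-fold lower. The 12 were the G-rich entries miR-638, miR-1202, miR-1915, miR-1225-5p, miR-1268, miR-1207-5p and miR-1275, with miR-1246, miR-1290, miR-923, miR-494 and miR-320a. The 4 were miR-1260, miR-1274a, miR-1274b and miR-574-3p. Other RNA that binds such probes would also recur in both lines, so the correlation cannot tell it from release of the named miRNAs. The difference between the 2 lines had a median of 0.04 and an SD of 0.81 over miRNAs, with 12 miRNAs at 1 or more and 5 at -1 or less. This is also the difference between the exosome and the cell comparisons of the lines, and it was not tested. The highest values, relatively more in PC3M exosomes, were those of miR-1260 (2.12, SD 0.19), miR-494 (1.81, SD 0.34), miR-720 (1.79, SD 0.15), miR-1280 (1.59, SD 0.32) and miR-1308 (1.51, SD 0.14), all but miR-494 from the entries that overlap other small RNAs. The lowest were miR-34a (-3.71, SD 0.24), miR-29b (-1.52, SD 0.09), miR-625 (-1.14, SD 0.37), let-7f (-1.11, SD 0.10) and miR-638 (-1.04, SD 0.19). Scaling over all miRNA probes moved the median to -1.21, with 0 miRNAs at 1 or more and 67 at -1 or less.

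**Figure D3:**
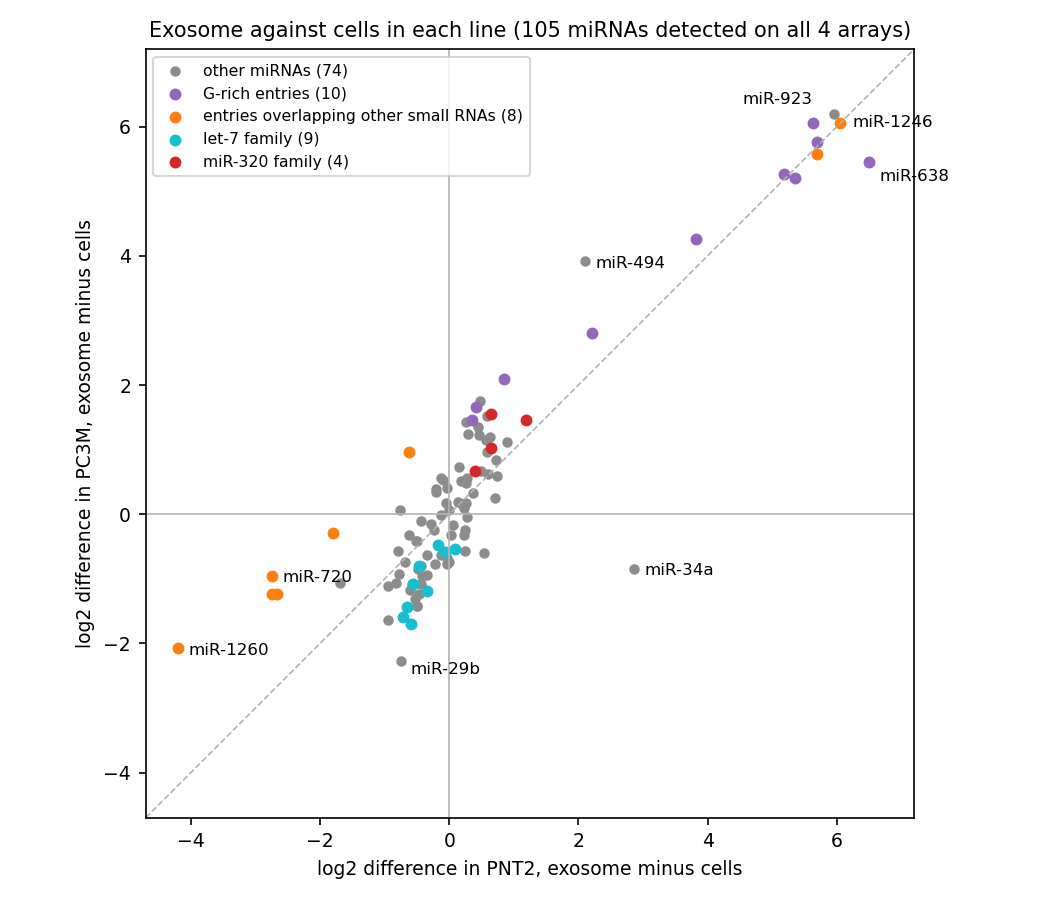
Log2 difference between exosomes and cells in PNT2 (x axis) and PC3M (y axis); each point is 1 of the 105 miRNAs detected on all 4 arrays, the dashed line marks equal differences, and 4 fixed groups are coloured. The G-rich entries extend to the upper right, with miR-638 at 6.50 and 5.45, and miR-34a lies at 2.86 and -0.84. Of the entries that overlap other small RNAs, miR-1260 lies at the lower left (-4.20 and -2.08) and miR-1280 at -0.63 and 0.96.

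Apart from neuron markers, markers of other cell types were rare. Of 7 blood cell markers only miR-451, a miRNA of red blood cells, was detected, at 42.7 ± 2.89 units in PNT2 exosomes and 47.6 ± 1.23 in PC3M exosomes. It was not well above background in either cell sample, so that it was at least 5.27-fold higher in PNT2 exosomes and at least 9.75-fold in PC3M exosomes. No muscle or liver marker was detected on any array. Of 9 pluripotent cell markers miR-371-5p was detected, on both exosome arrays only. Of 5 neuron markers 1 was detected in each exosome sample, 2 in PNT2 cells and 3 in PC3M cells.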

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

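All tests of explanations in this part were chosen only after the result was seen. The G-rich entries stood out as a group, since 7 of 11 measured in PNT2 and 11 of 11 in PC3M were at least 2-fold higher in exosomes than in cells, though 4 in PNT2 differed by less. Scaling does not account for the high median of the list, whose lowest value over the other scalings and both lines was 3.17. The PC3M count did depend on scaling. With scaling over all miRNA probes 7 of the 11 stayed at least 2-fold higher, and the lowest entry was at -0.44. Without scaling 8 stayed so, with quantile normalization 10 and with the median as reference 11. In PNT2 the count was 7 under each of these settings. A higher background does not account for the higher values of the group. The mean of the negative control spots was 0.979 units lower on the PC3M exosome array than on the cell array (-0.979, and -1.24 in PNT2). The median gain of the G-rich probes was 81.5 units in PC3M and 126 in PNT2. RNA other than the named miRNA may bind such probes: the viral probe kshv-miR-K12-3, made for a viral miRNA while the labels name no infection, was at least 77.3-fold higher in exosomes in PNT2 and at least 82.3-fold in PC3M, while ebv-miR-BART12 read 129 and 117 units in the cells and was not detected in exosomes. The first fits such binding but does not give its share of the G-rich signal, and a selective release of these RNAs stays open and was not tested.

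miR-34a was noted because its difference between PC3M and PNT2 had opposite signs, -1.77 in exosomes and 1.94 in cells, and the opposite difference was not tested. A single faulty probe does not account for it, because the other probe gave -1.55 in exosomes and 1.82 in cells, although there it was detected on 1 array of each pair. Both probes are made for the same miRNA, so their agreement cannot exclude another RNA that binds both. Scaling does not account for the opposite signs, as the smaller of both differences was still 1.47 in size under every other scaling. Exchanged labels of the exosome samples would turn most signs, but 19 of the 20 miRNAs with a 2-fold difference between the cells had the same sign in exosomes, and miR-34a was the 1 that did not. Over the 105 miRNAs detected on every array, 8 had opposite signs in exosomes and in cells, both beyond 2 combined spot SDs. A difference between the lines in how miR-34a is released is a hypothesis without replicates and was not tested.

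miR-451 drew attention as the 1 blood cell marker found, and only on exosome arrays. The medium held bovine serum per the labels, and RNA carried over from it could give this signal. At 3.68 times the lowest detected signal in PNT2 exosomes and 6.26 times in PC3M exosomes, miR-451 was dim. None of the other 6 blood cell markers was detected on both exosome arrays, with a highest signal of 11.8 units, so these values leave open whether serum was its source.

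Data outside the comparisons were read as well. Of 88 viral miRNAs on the array, 5 were detected in PNT2 exosomes, 4 in PC3M exosomes, 1 in PNT2 cells and 1 in PC3M cells. The brightest, kshv-miR-K12-3, read 626 units in PNT2 exosomes and 402 in PC3M exosomes. The array control hur_1 was higher in exosomes than in cells by log2 values of 3.63 in PNT2 and 3.67 in PC3M, and hur_4 by 3.79 and 4.70. What these control probes bind is not given in the sources used here. Single negative control spots spread more in exosomes (SD 6.60 and 9.48 units) than in cells (3.29 and 3.76), which is small beside the median gains of the probes of G-rich entries but leaves dim detections in exosomes in doubt. The viral and control probes were noted because no planned comparison used them.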

How the results depend on the processing

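Each group had 1 array, so no difference could be checked in a replicate, and agreement between probes or spots says nothing on how cultures vary. No paired analysis was made, since each comparison rests on 1 pair of arrays and no result came from a test. Pairing exosomes with cells over both lines would leave 2 pairs and take the normal and the cancer line as replicates of each other, which was not done. The deposited value table, planned as another source of values, could not be run because it holds errors of the signal. For the named miRNAs and list medians 2926 values were recomputed over the settings: 1529 stayed the same, 1388 moved and 9 were reversed. Of those that stayed the same, 246 came from leaving out the G-rich and other-small-RNA entries. That setting does not rescale the rest, so these values could not change. A reversal was counted where a named miRNA at 2-fold, or a median in the outer 5% of random lists, turned its sign. Over every miRNA at 2-fold, and not the named ones alone, 13 of the 27 higher values in PC3M exosome over cells kept their sign under each scaling. With the 75th percentile over all miRNA probes, the exosome comparison of the lines had 8 higher and 50 lower, the cell comparison 20 higher, PNT2 exosome over cells 42 lower and PC3M exosome over cells 11 higher and 82 lower. There the difference between the lines had a median of -1.21, with 0 miRNAs at 1 or more and 67 at -1 or less. The same setting reversed the median of miRNAs reported as higher in prostate tumours in exosomes (-0.16) and, in PC3M exosome over cells, miR-30d (-0.71), miR-320c (-0.35) and miR-320a (-0.44). In the same comparison the medians of the miR-320 (-0.66), miR-30 (-1.38) and miR-130 (-1.27) families also turned their sign, but lay nearer the middle of the random lists at first and are not among the 9. By construction it divides by a percentile that includes the undetected probes, so that the dim end of each array sets the scale. With the median as reference, 3 miRNAs had a difference between the lines of -1 or less. Without scaling, the exosome comparison had 12 higher and 42 lower, PNT2 exosome over cells 44 lower and PC3M exosome over cells 12 higher and 69 lower. The difference between the lines was then 1 or more for 3 and -1 or less for 39 miRNAs, and the median of the miR-320 family in PNT2 (-0.00863) and miR-30d in PC3M (-0.24) were reversed. With quantile normalization PNT2 had 27 lower and PC3M 15 higher and 37 lower. Normexp background correction left 13 higher and 7 lower in exosomes, 7 higher and 13 lower in cells, 5 lower in PNT2 and 8 lower in PC3M, with 6 and 3 miRNAs past 1 and -1 between the lines, and it reversed miR-29c in PC3M exosome over cells (0.0432). Its offset of 50 shrinks differences of dim probes by construction. Without the detection filter the exosome comparison had 38 higher and 42 lower, PNT2 36 higher and PC3M 92 higher, with 40 and 10 between the lines. The medians of miRNAs reported as higher in exosomes (-0.0242) and as lower in cells (-0.15) were counted as reversed. By construction these are the differences of the array floors, which undetected members take, and they do not describe the measured miRNAs. With the mean over all probes the exosome comparison had 15 higher. With Agilent's total gene signal it had 39 higher, PNT2 32 lower and PC3M 49 lower, with 22 and 13 between the lines. At 4-fold the counts were 6 higher and 3 lower in exosomes, 6 and 9 in cells, 4 lower in PNT2, 13 and 2 in PC3M, and 1 and 1 between the lines. Without the G-rich and other-small-RNA entries, a setting chosen after seeing the data, exosomes had 15 higher, PNT2 4 higher and 2 lower and PC3M 14 higher, with 3 at 1 or more between the lines. Detection in every spot moved 40 values and outlier-flagged spots kept moved 14, with 0 reversed in either. Apart from the effects of construction named here, the cause of these shifts was not tested.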

Other observations

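Passenger strands are the arms of a miRNA hairpin that are usually degraded. Of 170 on the array, 10 were detected in PNT2 exosomes, 8 in PC3M exosomes, 18 in PNT2 cells and 16 in PC3M cells. In PNT2 10 were detected only in cells and 2 only in exosomes, and in PC3M 12 and 4. By pattern, 14 miRNAs were detected in both cell samples and neither exosome sample, 5 of them passenger strands, with miR-374a, miR-148b and miR-33a among the rest. The reverse held for 21 miRNAs, 8 of them G-rich entries such as miR-671-5p and miR-939, with miR-654-5p and miR-451 among the others. These patterns rest on detection calls alone, the lowest detected scaled level was higher on the exosome arrays (log2 -4.74 and -4.76, against -5.26 and -5.40 in cells), and the negative control spots spread more on the exosome arrays.

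Some miRNAs of clusters that are silent in many adult tissues were detected in exosomes and not in cells. miR-654-5p, of the imprinted DLK1-DIO3 cluster, read 1003 ± 151 units in PNT2 exosomes and 1598 ± 210 in PC3M exosomes. miR-494, of the same cluster, was detected on all 4 arrays but was missing from the list fixed for it, so no count is given for the cluster. The X-linked miR-513a-5p read 37.1 ± 3.12 and 50.2 ± 4.68 units in the exosomes. miR-525-3p of the placental C19MC cluster was called detected in PC3M exosomes at 8.80 ± 12.3 units, which is within the spread of the negative controls of that array (SD 9.48). Since a viral probe was at least 77.3-fold higher in exosomes, these exosome-only signals may also come from other RNA that binds the probes, which was not tested for them.

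The 2 probes of miR-923 together made up 41.1% of the summed signal in PNT2 exosomes and 47.9% in PC3M exosomes, against 1.45% and 1.19% in the cells. A higher share of fragments of ribosomal RNA could lower the signal left for miRNAs when equal amounts of RNA are labelled. The scaling signal was 309 and 207 units in exosomes and 488 and 559 in cells, and without scaling 44 miRNAs were at least 2-fold lower in PNT2 exosomes than in cells. An amount of RNA per cell or per vesicle was not measured here, so every comparison of exosomes with cells is relative.

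The array controls did not move in 1 direction: hur_2 was lower in exosomes (-2.36 in PNT2, -2.56 in PC3M), as was hur_6 (-3.32, -3.0). The control miRNABrightCorner30 was lower too (-2.79, -2.64), while mr_1 was at -0.51 in PNT2 and 1.28 in PC3M. Controls hur_5 and dmr read under the lowest detected signal of every array. The cause of these differences was not tested.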
